A study of Mus musculus with 6 samples.

How the data were processed

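RNA was sequenced from Foxp3-GFP positive cells sorted from the livers of mice with autoimmune hepatitis (AIH) and of control mice, in 3 libraries per group that the titles number from 1 to 3 within each group; 1 control title is spelled differently from the other two. Per the labels' protocols, lysed cells were reverse transcribed and amplified by SMART-Seq2 (which copies polyadenylated RNA from small inputs into full-length cDNA), fragmented with a transposase and sequenced from DNA nanoballs. The protocol speaks of single cells, while each library is deposited as 1 sample with no map to cells, so each library was treated as 1 sample. How the disease was induced, how many cells or animals entered a library and whether libraries were made in batches are not given in the sources used here.

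Deposited were 1 table of genes and 1 of transcripts, with 4 kinds of values per library, named per the file headers. The read counts deposited by the authors were expected counts: 14.8 to 16.7% of them per library were not whole numbers, so reads had been shared between features, and they were not normalized. The TPM values, length-corrected per the file headers, summed to the same total in every library. The FPKM values deposited by the authors, which correct for length and depth, were not used, nor were the columns of group averages. The signal that the file headers call a normalized read count was made by the authors from the expected count rounded up to a whole number times 1 factor per library (1.09, 0.933 and 1.01 for AIH 1, AIH 2 and AIH 3, and 0.815, 1.05 and 0.799 for Control 1, Control 2 and Control 3), which held for 100% of genes within a relative tolerance of 1e-06 and equalled the inverse of DESeq2's size factors. FastQC, STAR, featureCounts and the builds GRCm39 and mm39 are named per the submitters' processing notes, without versions. The program that shared reads between transcripts, and its handling of reads that match several genes, are not given in the sources used here. The 15442 genes carried symbols and Entrez IDs, of which 15400 matched a RefSeq table of GRCm38.p6, 15376 of them with the same symbol and 15328 of them protein coding; of 37757 transcripts, all with RefSeq mRNA accessions, 36659 matched. Because that build differs from the one in the notes, no coordinates are given.

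Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16: TMM factors, the filter filterByExpr by group (minimum count 10, minimum total 15), a quasi-likelihood fit with the group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05 and no minimum fold. CPM were computed from TMM library sizes, and log2 fold changes are AIH minus control. SE is an approximate standard error, the absolute log2 fold change over the square root of the quasi-likelihood F statistic. It is rough for genes with few counts or a fold change near 0. The biological coefficient of variation was 0.948, with 4 residual and 5.45 prior degrees of freedom. The 40 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, for lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the 35 lists; camera with an estimated correlation and fry were alternatives. For each list the members' p-values from edgeR were also adjusted over the list alone. Transcripts were tested like genes, and transcript usage with diffSpliceDGE on the quasi-likelihood fit with Simes adjustment per gene, for genes with at least 2 transcripts past the filter; error in assigning reads to transcripts was not modelled.

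The named genes were fixed by rule: Foxp3, Il2ra, Ctla4, Ikzf2 and Il10 whatever their result, then up to 12 genes per direction with the smallest p among those past the threshold whose groups did not overlap, filled up to 5 per direction by the smallest p and described as not past. Members of the lists are given as examples of their list. Some members are not reported here by name. Ccl1 and Fcgr2b, and Penk, Sdf4, Cst7, Cd3g, Cd3d, Cd3e, Fasl and Skil in the other observations, were chosen after their values were seen. Samples, tests, lists, the rule and the alternative settings were fixed before the data were examined. The alternatives were DESeq2's size factors, library totals, no filter, a minimum of 10 CPM in 3 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0 and limma-voom. Chosen after seeing the data were a fit without AIH 1 and Control 3, which lay at the ends of the first principal component (32.5% of the variance), a fit with the mean log2 CPM of the macrophage list as a covariate, and a likelihood-ratio fit for usage. The macrophage mean was lower in every library labelled AIH than in every control. As a covariate it can therefore take up part of any group difference, whatever its cause. Pseudocounts and a filter on normalized values were planned in case the tables held no counts, and were not run.

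Totals of 17780509 to 24572388 counts put the floor of 3 counts at 0.115 to 0.160 CPM. With 3 against 3 libraries an exact two-sided permutation test could not go below 0.1, so no single value was tested that way. No pair of libraries was alike within sampling noise: the chi-square statistic per degree of freedom lay between 173 and 612. The tests were tested on simulated data with the means, library sizes and spread of these libraries. With 200 of 11140 genes changed in each of 5 simulations, the gene test recovered 0% of genes changed 2-fold, 9.64% of those changed 4-fold and 37.2% of those changed 8-fold, with 5.92% false calls. Over 17999 transcripts it recovered 0, 0 and 0.901%, and 95.5, 99.7 and 100% with a coefficient of variation of 0.1. Camera found 13 of 15 lists shifted by 1 on the log2 scale and called 1 of 143 lists with no shifted member. Genes were drawn independently there, so these counts do not cover lists whose members move together. The macrophage list, for example, had an estimated correlation of 0.625 in these libraries. The usage test found 0 of 200 swapped genes at the spread of these libraries and 200 of 200 at a coefficient of 0.1, over 3779 genes.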

Results

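Gene expression was measured by RNA sequencing in cells sorted from mouse liver for green fluorescence of a reporter of Foxp3, the transcription factor of regulatory T cells (Treg cells, CD4 T cells that restrain immune responses). Of the 6 libraries, 3 were labelled AIH, from a mouse model of autoimmune hepatitis (a disease in which the immune system attacks the liver), and 3 were labelled control. The libraries held 20916065, 22440306 and 22054917 expected counts in AIH 1, AIH 2 and AIH 3, and 24572388, 17780509 and 23920354 in Control 1, Control 2 and Control 3. Between 11722 and 12645 of the 15442 genes in the table had a count of at least 1 in a library. Pearson's correlation of log2 CPM (counts scaled to a common library total) across genes, which are not independent replicates, was 0.792 to 0.826 between AIH libraries, 0.763 to 0.836 between control libraries and 0.683 to 0.837 between the groups. No label says that the libraries came from separate animals, so the p-values measure only the spread between these samples. The comparison of AIH with control addressed how liver cells sorted for the Foxp3 reporter differ in the disease.

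Foxp3 (Entrez ID 20371), the transcription factor that defines Treg cells and the gene behind the sort, was counted 5, 91 and 32 times in AIH 1, AIH 2 and AIH 3, and 418, 274 and 1002 times in Control 1, Control 2 and Control 3. Its mean level was 1.98 ± 1.97 CPM in the libraries labelled AIH and 23.1 ± 13.2 CPM in the control libraries (SD, n = 3 per group), a log2 fold change of −3.54 (SE 1.24). The adjusted p was 0.501 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The groups did not overlap, which chance gives for 10% of genes in either direction and which 17.3% of all genes tested showed. A low Foxp3 level goes against the sort named in the labels, so these are called the libraries labelled AIH, and each direction below rests on those labels. The log2 fold change lay between −4.64 without AIH 2 and −2.96 without Control 3 with any 1 library left out, was −2.45 without AIH 1 and Control 3 together and −1.58 (SE 1.51) with the mean of the macrophage genes as a covariate. The adjusted p of Foxp3 ranged over 15 alternatives from 0.0326 with DESeq2's Wald test to 0.9996 with that covariate.

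Other genes that characterise Treg cells did not pass the test. Il2ra (16184), which encodes the alpha chain of the interleukin-2 receptor, was at 183 ± 76.9 CPM in the libraries labelled AIH and 188 ± 40.6 CPM in the controls (SD, n = 3), with a log2 fold change of −0.04 (SE 0.36). Ctla4 (12477), an inhibitory receptor, was at 472 ± 223 and 350.3 ± 104 CPM, a log2 fold change of 0.43 (SE 0.37). Ikzf2 (22779), which encodes the transcription factor Helios, was at 811 ± 341 and 579 ± 111 CPM, a log2 fold change of 0.49 (SE 0.33). With the macrophage covariate Il2ra stood at 0.71 (SE 0.40) and Ikzf2 at −0.13 (SE 0.43), and Ctla4 stood at −0.032 without AIH 2. Il10 (16153), the gene of an anti-inflammatory cytokine, was at 92.0 ± 82.1 and 3.61 ± 3.78 CPM, a log2 fold change of 4.67 (SE 1.44), with counts of 1057, 4097 and 692 in the libraries labelled AIH and 187, 64 and 0 in the controls. Their adjusted p-values by edgeR's quasi-likelihood test were 0.991, 0.838, 0.774 and 0.449 after Benjamini-Hochberg adjustment; that of Il10 ranged over 15 alternatives from 0.0104 with DESeq2's Wald test to 0.9996 with the macrophage covariate. The log2 fold change of Il10 was 3.64 without AIH 2, 5.82 without Control 1, 5.77 with the replicate block, 3.71 (SE 2.29) with the covariate and 6.64 by limma-voom. Over the Treg identity list, 13 of 21 tested members had a positive log2 fold change, with a median of 0.39 (0.15 without AIH 3) and an adjusted p of 0.188 by camera. No member passed over all genes tested. Adjusted over the list alone, 3 did, the costimulatory receptor genes Tnfrsf4 at 1746 ± 491 against 287 ± 163 CPM, Tnfrsf18 at 1790.2 ± 444 against 473 ± 209 CPM, and Tnfrsf9 at 248 ± 115 against 42.2 ± 26.6 CPM.

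**Figure D1:**
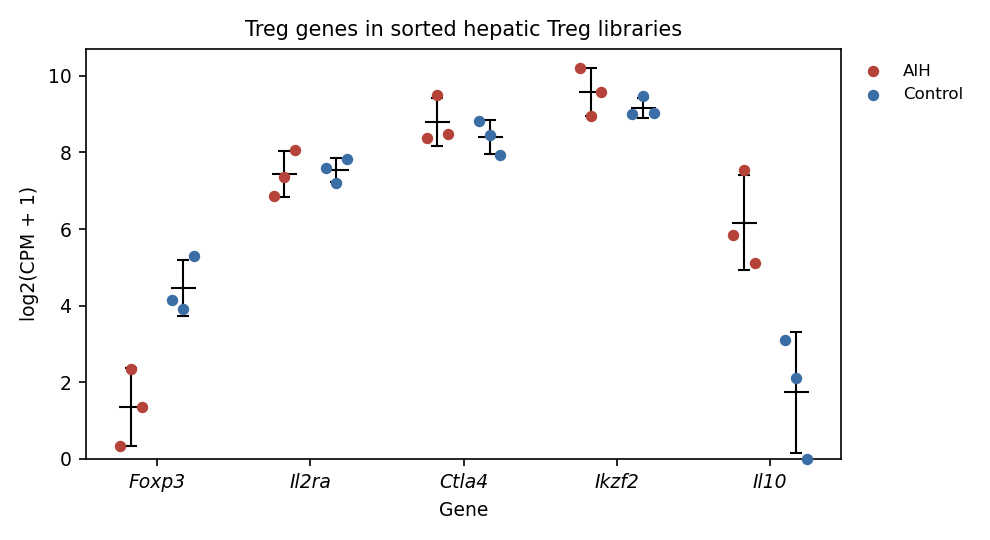
Expression of Foxp3, Il2ra, Ctla4, Ikzf2 and Il10 as log2(CPM + 1) on the vertical axis, with 1 point per library, red for the 3 libraries labelled AIH and blue for the 3 controls; black bars give the mean ± SD (n = 3). The Foxp3 points of the libraries labelled AIH lie below all control points and the Il10 points above them, while the points of Il2ra, Ctla4 and Ikzf2 overlap between the groups.

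The chemokine genes Ccl5, Ccl3 and Xcl1 and the nuclear receptor gene Nr4a2 rose in the libraries labelled AIH. Ccl5 (20304), which attracts T cells and other leukocytes, rose from 259 ± 154 CPM in the controls to 3815 ± 1791 CPM (SD, n = 3 per group), a log2 fold change of 3.88 (SE 0.54). Ccl3 (20302), a chemokine gene that is switched on in activated immune cells, rose from 24.7 ± 7.86 to 338 ± 136 CPM, a log2 fold change of 3.77 (SE 0.43). Xcl1 (16963), whose product attracts cross-presenting dendritic cells, rose from 12.8 ± 6.72 to 255 ± 158 CPM, a log2 fold change of 4.32 (SE 0.59) that was 3.68 without AIH 3. Nr4a2 (18227), an orphan nuclear receptor gene that T cell receptor signals induce, rose from 0.11 ± 0.0803 to 34.5 ± 5.86 CPM, a log2 fold change of 8.20 (SE 1.09). Its counts summed to 8 over the 3 control libraries and to 2109 over those labelled AIH, a ratio of 302 in CPM with an exact 95% counting interval of 153 to 701. This interval treats reads as independent and leaves out the spread between libraries. The reads carry no molecular identifiers, so amplified copies are not told apart. Intervals and detection floors may therefore understate even the counting error.

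The other genes that passed were Id2, Samsn1, Bcl2a1d, Serpina3g and Mmd, which rose, and Klf2, which fell. Id2 (15902), a regulator of effector and tissue-resident lymphocytes, rose from 305 ± 44.8 to 1089.8 ± 103 CPM (SD, n = 3 per group), a log2 fold change of 1.84 (SE 0.25). Samsn1 (67742), an adaptor protein gene of lymphocytes, rose from 135 ± 42.8 to 892 ± 82.8 CPM, a log2 fold change of 2.72 (SE 0.31). Bcl2a1d (12047), of the anti-apoptotic Bcl2a1 family, rose from 77.3 ± 19.6 to 393 ± 10.3 CPM; its value is uncertain because near-identical paralogs share reads. Serpina3g (20715), a serine protease inhibitor gene of activated lymphocytes, rose from 78.1 ± 7.66 to 323 ± 58.6 CPM, and Mmd (67468) from 43.8 ± 9.14 to 224 ± 24.1 CPM. Klf2 (16598), a transcription factor that maintains T cell quiescence and exit from lymphoid organs, fell from 303 ± 62.4 to 44.3 ± 4.45 CPM, a log2 fold change of −2.77 (SE 0.31).

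**Figure D2:**
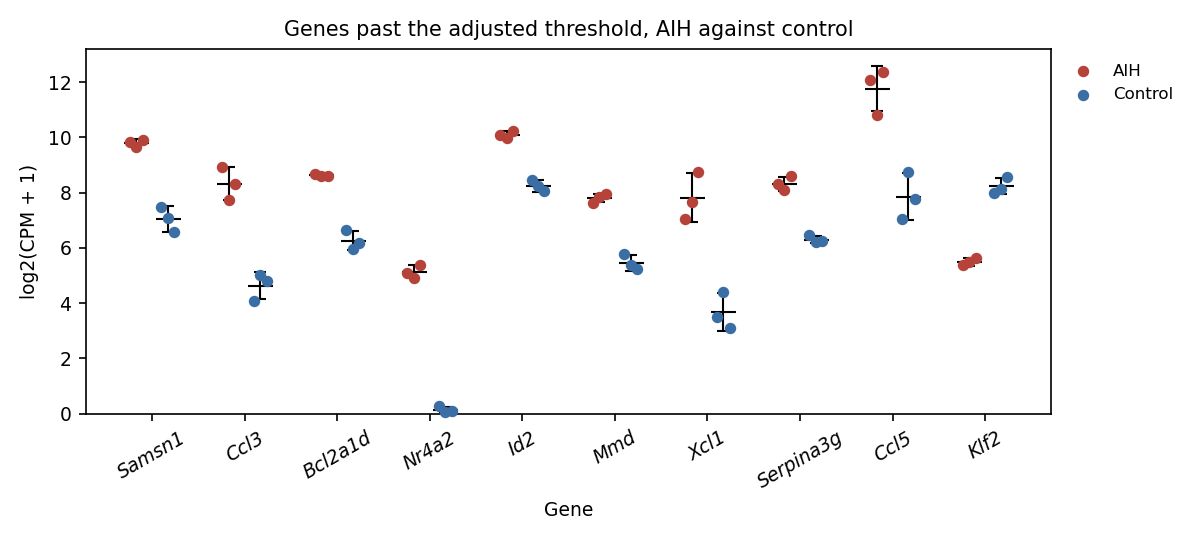
The 10 genes past the adjusted threshold as log2(CPM + 1), with 1 point per library, red for the 3 libraries labelled AIH and blue for the 3 controls; black bars give the mean ± SD (n = 3). For Samsn1, Ccl3, Bcl2a1d, Nr4a2, Id2, Mmd, Xcl1, Serpina3g and Ccl5 all points of the libraries labelled AIH lie above all control points, and for Klf2 below them.

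Of 11140 genes tested, these 9 rose and 1 fell at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p-values from 0.0281 (Klf2, Ccl3 and Samsn1) to 0.0448. At an unadjusted p under 0.05, 492 genes were higher and 429 lower, where chance gives 557 in all. In 1930 genes (17.3%) the groups did not overlap, where chance gives 10%. Among the lower genes with the smallest p, none besides Klf2 passed: H2-Ab1 (14961) and H2-Eb1 (14969), which encode major histocompatibility complex (MHC) class II chains, were at 255 ± 36.4 against 863 ± 189.7 CPM and at 145 ± 57.3 against 683 ± 183 CPM in the controls. Mpeg1 (17476) and Ly86 (17084), genes of macrophages and B cells, were at 92.8 ± 18.9 against 339 ± 132 CPM and at 110.5 ± 33.4 against 407 ± 154 CPM. The log2 fold changes of these 4 genes were −1.76, −2.23, −1.87 and −1.88, with adjusted p-values of 0.0883, 0.108, 0.193 and 0.227. With the mean of the macrophage list as a covariate they stood at −1.42 (SE 0.38), −1.44 (SE 0.38), −1.35 (SE 0.50) and −1.004 (SE 0.38). In the same libraries the macrophage genes were low, with a mean log2 CPM over the macrophage list of 2.22, 4.97 and 5.88 in AIH 1, AIH 2 and AIH 3 against 7.20, 6.09 and 9.17 in Control 1, Control 2 and Control 3. None of the 10 calls remained when any 1 library was left out, where edgeR's quasi-likelihood test called 1 gene without AIH 1 (Ccl1, higher), 1 without AIH 3 (Fcgr2b, lower) and 0 without AIH 2, Control 1, Control 2 or Control 3. With that macrophage mean as a covariate 0 genes were called, with log2 fold changes of 2.51 (SE 0.42) for Samsn1, 1.79 (SE 0.36) for Id2, 4.48 (SE 0.72) for Xcl1, 3.56 (SE 0.68) for Ccl5, 3.29 (SE 0.56) for Ccl3 and −2.45 (SE 0.42) for Klf2. Without AIH 1 and Control 3 together 1 gene was called, with library totals as the scaling 3 (2 higher and 1 lower), without the filter 32, by limma-voom 21 and by DESeq2 337, of which 170 were higher.

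Genes of resting and recirculating T cells fell as a group in the libraries labelled AIH. Of the 16 tested members of the resting and lymphoid T cell programme, 15 had a negative log2 fold change, with a median of −1.39. Besides Klf2, Ccr7, the chemokine receptor that guides T cells into lymph nodes, was at 51.1 ± 24.3 against 170.2 ± 47.6 CPM in the controls (SD, n = 3 per group). Bach2, a repressor of effector differentiation, was at 4.91 ± 2.43 against 44.5 ± 28.8 CPM, and Satb1, a chromatin organiser of T cells, at 34.0 ± 10.5 against 130.3 ± 65.0 CPM. Camera gave the list an adjusted p of 3.70e-07, and the adjusted p was 0.143 with an estimated correlation. That correlation was 0.00508, below the preset 0.01, so members that move together do not account for the lost call. Klf2 was the 1 member called over all genes tested, and 10 members were lower adjusted over the list alone. The groups did not overlap for 12 members, where chance gives 10% and 17.3% of all genes tested showed it. Of the 16 genes, 5 stand in another list too.

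Genes of Treg suppression and inhibitory receptors rose as a group, with a positive log2 fold change for 17 of 19 members and a median of 1.01. Adjusted over the list alone 5 members were higher, and over all genes tested none was. Fgl2, which encodes a soluble suppressor protein of Treg cells, had a log2 fold change of 1.94 (SE 0.33), and Tigit, an inhibitory receptor, was at 1122 ± 314 against 261 ± 137 CPM. Pdcd1, which encodes the inhibitory receptor PD-1, was at 49.0 ± 34.9 against 3.49 ± 2.83 CPM. Cd160 and Il10 were the others. The adjusted p was 1.71e-05 by camera, 0.341 with an estimated correlation and 0.0552 with the macrophage mean as a covariate. The median was 0.35 without AIH 2, 0.65 without Control 3 and 0.41 with a filter at 10 CPM in 3 libraries. Of the 19 genes, 9 stand in another list.

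The tissue and effector Treg programme rose as a group, with a positive log2 fold change for 15 of 21 members and a median of 0.61. Id2 was its 1 member called over all genes tested; adjusted over the list alone, Id2, Ccr8, Cxcr6, Tnfrsf9, Batf and Il10, 6 in all, were higher. Ccr8, a chemokine receptor of tissue Treg cells, was at 279.7 ± 131 against 21.6 ± 14.1 CPM (SD, n = 3 per group), Cxcr6, a receptor of liver-resident lymphocytes, at 393 ± 108 against 71.6 ± 43.3 CPM, and Batf, a transcription factor of effector Treg cells, at 399.6 ± 133 against 181 ± 55.3 CPM. Il1rl1, which encodes the interleukin-33 receptor of tissue Treg cells, had the opposite sign, at 24.5 ± 15.9 against 69.7 ± 29.8 CPM. Camera gave an adjusted p of 0.000197, with adjusted p = 0.404 with an estimated correlation and 0.260 with the macrophage mean as a covariate. The median was 0.40 without AIH 3 and 1.01 without Control 2, and 11 of the 21 genes stand in another list.

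Th1-type genes, those of inflammatory T cells that make interferon gamma, rose as a group, with a positive log2 fold change for 12 of 20 members and a median of 0.54. Ccl3, Xcl1 and Ccl5 were called over all genes tested, and 8 members were higher adjusted over the list alone, among them Ifng, the interferon gamma gene itself, at 47.4 ± 24.1 against 6.95 ± 2.89 CPM, and Nkg7, a gene of cytotoxic granules, at 1560 ± 57.0 against 316 ± 184 CPM. In 7 members every library labelled AIH lay above every control, and in 3, Il12rb1 and Il18rap among them, below. The groups did not overlap for 17.3% of all genes tested. None of the 3 lower members passed either count. Tbx21, which encodes the Th1 transcription factor T-bet, had a log2 fold change of −0.10 (SE 1.98). Cd8a, a gene of CD8 T cells, which carry many of these genes too, was also higher in every library labelled AIH than in every control (log2 fold change 2.53, SE 0.57), while the groups overlapped for Cd8b1. The adjusted p was 0.000488 by camera, 0.379 with an estimated correlation, 0.260 with the macrophage mean as a covariate and 0.0723 without AIH 1 and Control 3. The median moved to 0.26 without AIH 1, 1.30 without Control 1, 1.03 without Control 2 and 0.00 without Control 3. It was 0.34 with library totals as the scaling, 0.86 with a filter at 10 CPM, 0.08 with the covariate and 0.02 without AIH 1 and Control 3, and 5 of the 20 genes stand in another list.

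Immediate early genes, which T cell receptor signals switch on, rose as a group, with a positive log2 fold change for 17 of 23 members and a median of 0.62. Nr4a2 was called over all genes tested; adjusted over the list alone, 6 members were higher, with Nr4a3 at 51.6 ± 32.3 against 0.228 ± 0.395 CPM, Egr2 at 25.2 ± 8.81 against 0.658 ± 0.876 CPM and Rgs1, a regulator of chemokine receptor signalling, at 1277 ± 464 against 426 ± 152 CPM (SD, n = 3 per group). Fos, Jun and Junb, of the AP-1 family, had log2 fold changes of −0.38, 0.09 and 0.20. Camera gave an adjusted p of 0.000437, with adjusted p = 0.280 with an estimated correlation, and the median was 0.36 without AIH 2 and 0.38 without Control 3. Genes of the NF-kB and TNF response rose as a group too, with a positive log2 fold change for 12 of 19 members, a median of 0.70 and an adjusted p of 0.00560 by camera, against 0.280 with an estimated correlation and 0.260 with the macrophage mean as a covariate. None of its members passed over all genes tested, and 2 were higher adjusted over the list alone, the inhibitor genes Nfkbid at 64.6 ± 28.2 against 11.7 ± 1.92 CPM and Nfkbia at 401 ± 56.5 against 183 ± 33.2 CPM. The median was 0.46 without AIH 1, and 2 of the 19 genes stand in another list. The macrophage genes were low and Cd8a high in the same libraries in which these 5 groups of T cell genes were high and the resting genes low.

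**Figure D3:**
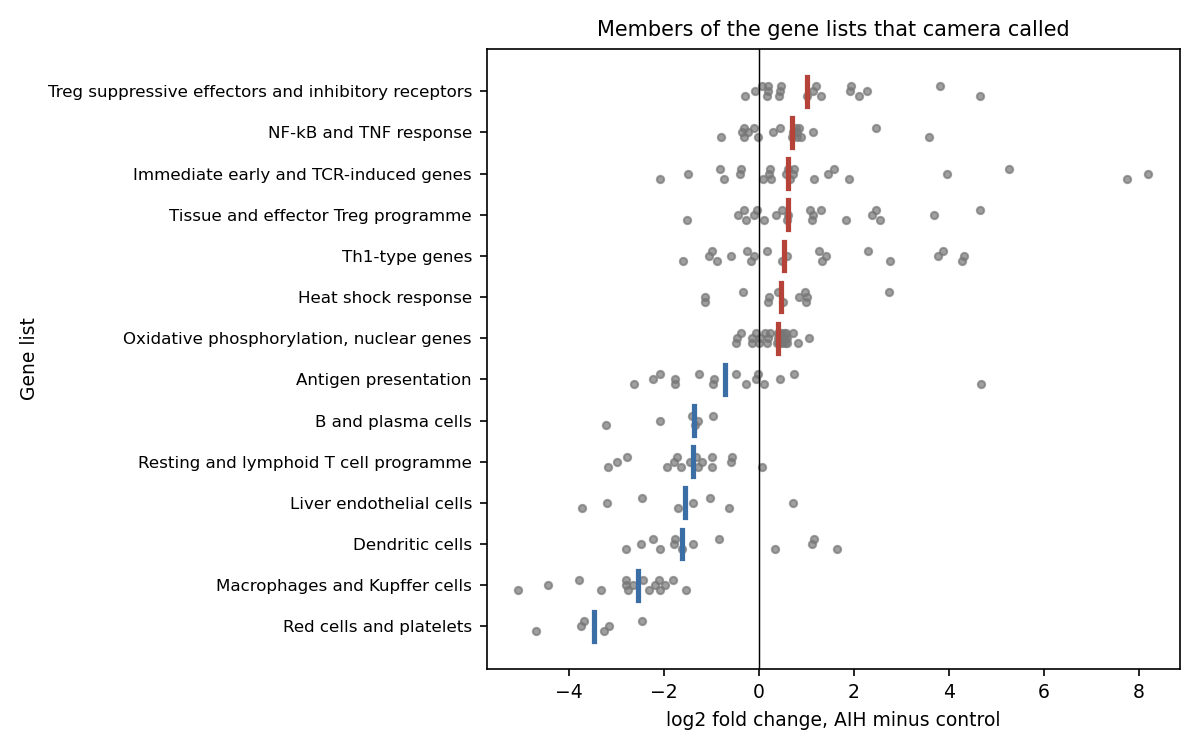
Log2 fold changes (AIH minus control, horizontal axis) of the members of the 14 gene lists that camera called, with 1 grey point per tested gene; vertical bars mark each list's median, red where the test was up and blue where it was down. The medians run from −3.48 for red cells and platelets to 1.01 for Treg suppression, and the members of most lists lie on both sides of 0.

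Nuclear genes of oxidative phosphorylation, the mitochondrial respiratory chain, rose as a group, with a positive log2 fold change for 23 of 29 members and a median of 0.41; Cycs, which encodes cytochrome c, was at 887 ± 178 against 499 ± 115 CPM (SD, n = 3 per group). No member passed over all genes tested or adjusted over the list alone. The adjusted p was 0.0286 by camera, 0.404 with an estimated correlation, 0.102 with library totals as the scaling and 0.531 with the macrophage mean as a covariate; without AIH 1, AIH 3, Control 1, Control 2 or Control 3 it was 0.135, 0.0626, 0.0604, 0.0935 and 0.0646. The median was 0.22 with library totals, 0.13 with the covariate and 0.16 without AIH 1 and Control 3. The macrophage genes were low in the libraries in which these genes were high. Heat shock genes, which encode protein chaperones, were higher for 9 of 12 members with a median of 0.46. Hspe1 was at 299 ± 51.5 against 149 ± 5.26 CPM and Dnaja1 at 594 ± 155 against 304 ± 9.34 CPM, the 2 members higher adjusted over the list alone, with none over all genes tested. Camera's adjusted p of 0.0354 became 0.379 with an estimated correlation, and 0.0538, 0.0756, 0.221, 0.0951 and 0.261 without AIH 1, AIH 2, AIH 3, Control 1 or Control 2. The list passed with the macrophage mean as a covariate (adjusted p = 0.0277, median 0.84), and its median was 0.26 with library totals and 0.78 without AIH 1 and Control 3. Its mean log2 CPM overlapped between the groups, at 5.64, 5.88 and 6.82 in AIH 1, AIH 2 and AIH 3 and 5.96, 5.01 and 5.88 in Control 1, Control 2 and Control 3.

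Macrophage and Kupffer cell genes fell as a group in the libraries labelled AIH, with all 16 tested members at a negative log2 fold change and a median of −2.55. C1qb, a complement gene of macrophages, was at 394 ± 253 against 1790.9 ± 1370.3 CPM in the controls (SD, n = 3 per group), and Lyz2, the lysozyme gene of myeloid cells, at 606 ± 562 against 2572 ± 1126 CPM. Clec4f, a lectin gene of Kupffer cells, the resident macrophages of the liver, was at 57.0 ± 40.3 against 573 ± 660.3 CPM. No member passed over all genes tested, and 9 were lower adjusted over the list alone. For 10 members the groups did not overlap, where chance gives 10% and 17.3% of all genes tested showed it. The members moved together, with an estimated correlation of 0.625, so they are not independent of each other. Camera's adjusted p was 1.14e-06, and the adjusted p was 0.404 with an estimated correlation. The list's median was −1.23 without Control 3, which held the highest macrophage mean, and −0.85 without AIH 1 and Control 3. With the list's own mean as a covariate it was −0.15 (adjusted p = 0.985 by camera). That outcome was set in advance, since the covariate takes out the list's own difference.

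Antigen presentation genes fell as a group, most clearly those of MHC class II. The class II genes H2-Ab1, H2-Eb1, H2-Aa, H2-DMb1, H2-DMa and Cd74 were the 6 members lower adjusted over the list alone, with H2-Aa at 553 ± 401 against 2349 ± 387 CPM and Cd74, the class II invariant chain, at 986 ± 526 against 3377 ± 756 CPM (SD, n = 3 per group). B2m, the light chain of class I, was the 1 member higher adjusted over the list alone, with a log2 fold change of 0.74 (SE 0.22). This 1 gene does not show a rise of class I genes. No member of the list passed over all genes tested. The list's median was −0.72 over 16 members, of which 12 were negative and 6 stand in another list. Its adjusted p was 0.0286 by camera, 0.404 with an estimated correlation and 0.287 with the macrophage mean as a covariate, and 0.0787, 0.0769, 0.0604 and 0.197 without AIH 2, AIH 3, Control 1 or Control 3; the median was −0.34 without Control 3 and −0.46 (adjusted p = 0.191) without AIH 1 and Control 3. Dendritic cell genes, 4 of 13 of which stand in another list, had a median of −1.62, and the 3 lower adjusted over the list alone were H2-Ab1, H2-Eb1 and H2-Aa. Camera's adjusted p for them was 0.0258, against 0.341 with an estimated correlation, 0.0644 without AIH 2, 0.275 without AIH 3, with a median of −1.07, and 0.0652 without Control 1.

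By camera, genes of B cells, endothelial cells and blood were lower as groups as well. The mean log2 CPM of the B cell list overlapped between the groups, at 3.22 in AIH 3 and 3.06 in Control 3. That of the red cell list did too, at 4.19 in AIH 3 against 3.62 and 3.80 in Control 1 and Control 2. The 6 B and plasma cell genes had a median log2 fold change of −1.37, all 6 negative, with Cd79b, a B cell receptor component, at 43.7 ± 6.09 against 110.5 ± 5.33 CPM (SD, n = 3 per group) as the 1 member lower adjusted over the list alone. Liver endothelial genes had a median of −1.55 over 8 members, and genes of red cells and platelets a median of −3.48 over 6. Neither had a member past the test adjusted over the list alone, and no member of the 3 lists passed over all genes tested. Camera's adjusted p was 0.0225, 0.0258 and 0.0258 for the 3 lists, and 0.379, 0.469 and 0.469 with an estimated correlation. With the macrophage mean as a covariate the 3 calls were lost, at adjusted p-values of 0.142, 0.958 and 0.958 and medians of −0.89, −0.50 and 0.54, so the red cell median took the other sign. Without AIH 1 and Control 3 the endothelial median was −0.69 (adjusted p = 0.463) and the red cell median 0.09 (0.262). The B cell call of camera in limma was lost without Control 1 (adjusted p = 0.0652) or Control 2 (0.0545), and its median was −3.26 without AIH 3. The endothelial call was lost without Control 2 (0.0520) or Control 3 (0.118), and its median was −4.11 without AIH 2, −3.42 without AIH 3 and −2.20 without Control 1. Hbb-bs, a globin gene, was at 31.0, 4.04 and 92.8 CPM in AIH 1, AIH 2 and AIH 3 and at 31.1, 24.8 and 1666 CPM in Control 1, Control 2 and Control 3; the red cell median was −0.28 without Control 3 (camera's adjusted p = 0.246), −5.01 without AIH 3 and −3.06 without AIH 2 (adjusted p = 0.148).

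**Figure D4:**
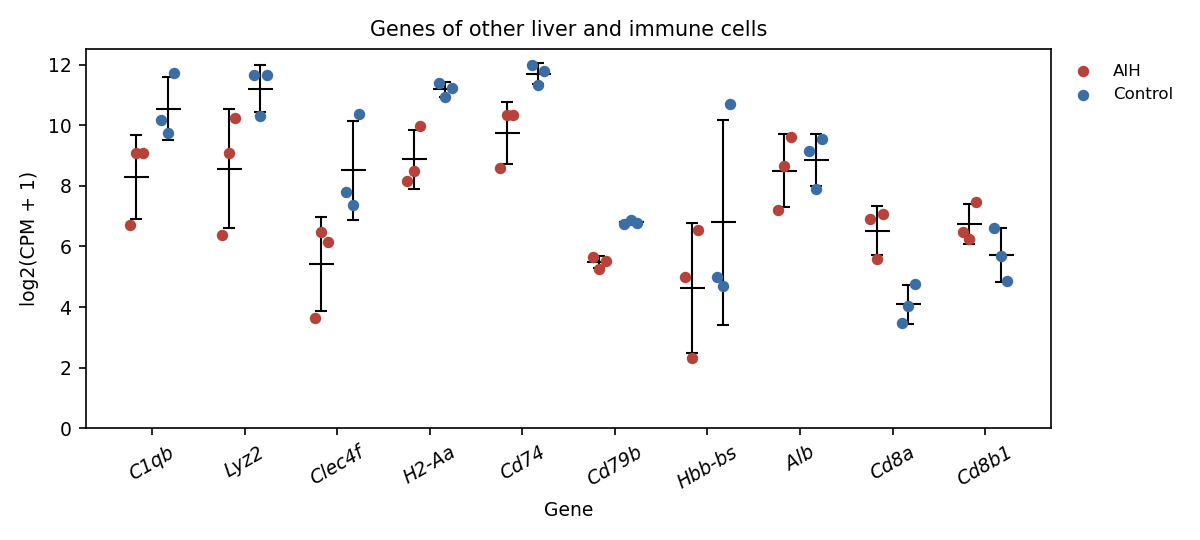
Genes of macrophages (C1qb, Lyz2, Clec4f), antigen-presenting cells (H2-Aa, Cd74), B cells (Cd79b), red cells (Hbb-bs), hepatocytes (Alb) and CD8 T cells (Cd8a, Cd8b1) as log2(CPM + 1), with 1 point per library, red for the 3 libraries labelled AIH and blue for the 3 controls; black bars give the mean ± SD (n = 3). The macrophage, class II and Cd79b points of the libraries labelled AIH lie below all control points and the Cd8a points above them, while the points of Hbb-bs, Alb and Cd8b1 overlap between the groups.

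Of the 40 lists fixed before the data were examined, 35 had the 5 tested members a list test needs, and camera with its preset correlation called 7 higher and 7 lower. With an estimated correlation 0 lists were called, and by fry 3, which were the resting, NF-kB and immediate early lists. The estimated correlation was 0.00508 for the resting, −0.0320 for the NF-kB and −0.0191 for the dendritic cell list. These lie below the preset 0.01, so members that move together do not account for those lost calls. For the other called lists the estimate lay above 0.01. With the macrophage mean as a covariate 5 lists were called, with 4 of the 14 among them. The loss of the macrophage list itself was set in advance, since its own mean was the covariate. For the other lists a lost call does not show macrophage RNA as the cause. The covariate separated the groups and can take up any difference between them. Without Control 1, 9 lists were called, all of them among the 14; without any other single library 11 to 14 were called, with 10 to 12 of the 14 among them. Library totals in place of TMM (trimmed mean of M-values) factors moved the median log2 fold change of all genes from −0.04 to −0.23.

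Cytokine genes of conventional CD4 T cells and genes of CD8 T cells had too few tested members for a list test in the fit of all 6 libraries. The CD4 cytokine list reached 5 tested members without AIH 1, AIH 3, Control 2 or Control 3, and without AIH 1 and Control 3 together. Camera called it higher in these fits, with adjusted p-values of 0.00641, 0.000658, 0.0102, 0.00469 and 0.0187 and medians of 2.29, 2.86, 2.69, 3.004 and 2.66. The added member passed the filter only with fewer libraries, and the fits share most of their libraries. An estimated correlation was not run for them, so no conclusion is drawn from these calls. Ifng, Csf2, Tnf and Cd40lg had log2 fold changes of 2.77, 5.80, 3.58 and 0.76, of which Ifng and Csf2 passed adjusted over the list alone (adjusted p = 0.012 and 0.022 by edgeR's quasi-likelihood test). Cd8a, which encodes a chain of the CD8 co-receptor, was at 119, 46.8 and 132 CPM in AIH 1, AIH 2 and AIH 3 and at 9.99, 15.3 and 26.3 CPM in Control 1, Control 2 and Control 3. Cd8b1, the other chain, was at 87.6, 75.1 and 177 CPM and at 97.4, 49.8 and 27.9 CPM. Cd4, the co-receptor of Treg cells, was at 49.3, 93.3 and 28.3 CPM and at 109, 82.0 and 80.7 CPM. Epcam, the 1 cholangiocyte gene tested, had a log2 fold change of 2.16 (SE 0.83), and Ms4a2, the 1 mast cell gene tested, of 3.82 (SE 2.32). Of the mitochondrially encoded genes 0 were in the table.

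Genes of several other programmes did not pass as groups in the fit of all 6 libraries, although proliferation and hepatocyte genes did under alternatives. Proliferation genes had a median log2 fold change of 0.20 and an adjusted p of 0.0690 by camera, with Cdk1 at 80.3 ± 7.68 against 34.3 ± 14.3 CPM and Mki67 at 86.2 ± 68.2 against 93.5 ± 23.2 CPM (SD, n = 3 per group). Camera called the list higher without AIH 2 (adjusted p = 0.0316, median 0.29) and without Control 2 (0.0332, median 0.25). The median was 0.07 without AIH 1 (0.461), 0.04 with library totals, −0.0026 without AIH 1 and Control 3 together (0.676) and −0.16 with a downward test with the macrophage covariate (0.958). Hepatocyte genes had a median of −0.33 (adjusted p = 0.497), with Alb, the albumin gene, at 443 ± 317 against 515 ± 256 CPM. Camera called them lower without AIH 3 (adjusted p = 0.0179, median −0.98) and Control 2 (0.0156, median −0.64), but higher with the macrophage covariate (3.40e-09, median 1.39) and without AIH 1 and Control 3 together (0.00486, median 0.58), and their median was 0.11 without AIH 1 and 0.18 without Control 3. Genes of NK cells and type 1 innate lymphoid cells had a median of 0.15 (0.828), which took the other sign without AIH 1 (−1.31), Control 2 (−0.20) or Control 3 (−0.72). Their mean log2 CPM was 6.65, 3.17 and 4.63 in AIH 1, AIH 2 and AIH 3 and 5.84, 5.12 and 2.94 in Control 1, Control 2 and Control 3. Genes of monocytes and neutrophils had a median of 0.34 and a mean of 0.08 with a downward test (0.906), and a median of −0.24 without AIH 3. Type I interferon-stimulated genes had a median of −0.15 (0.356), which was 0.09 without AIH 1, 0.07 without Control 3, 0.15 without both and 0.30 with an upward test with the covariate. Interferon gamma-induced genes had a median of −0.04 with an upward test (0.803), which was 0.07, 0.08, 0.05 and 0.15 without AIH 1, AIH 3, Control 1 or Control 3. Chemokine receptor and adhesion genes had a median of −0.65 (0.267), with Ccr8, Cxcr6 and Cxcr3 higher and Ccr7 lower adjusted over the list alone. Th17-type genes had a median of −0.33 (0.474), Th2-type genes −0.29 with a mean of 0.21 and an upward test (0.765), and follicular T cell genes −0.51 (0.741). T cell receptor signalling genes had a median of 0.04 with a mean of −0.03 (0.850), IL-2 and STAT5 signalling genes −0.07 (0.890) and TGF-beta signalling genes 0.11 (0.663). The T cell receptor median was −0.04, −0.04, −0.02 and −0.08 without AIH 1, AIH 3, Control 1 or Control 3, and the TGF-beta median −0.02 without Control 3. With the covariate the follicular and IL-2 medians were 0.10 and 0.06.

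Metabolic and stress programmes did not pass in that fit either. Fatty acid genes had a median log2 fold change of −0.57 (adjusted p = 0.0996 by camera) and were called lower without AIH 3 (adjusted p = 0.00700, median −0.78), while the median was −0.27 without Control 3 (0.230) and −0.09 with the macrophage covariate (0.958). Glycolysis genes had a median of −0.24 (0.189) and cholesterol genes −0.50 (0.656). Unfolded protein response genes had a median of 0.27 (0.656), oxidative stress genes 0.08 with a mean of −0.07 and an upward test (0.906), and apoptosis genes −0.05 with a mean of 0.02 and an upward test (0.474). Stellate cell genes had a median of −0.21 with an upward test (0.147) and a mean of 0.88 with Hgf at its bound, since Hgf was counted 133, 185 and 222 times in AIH 1, AIH 2 and AIH 3 and 0 times in the controls. Camera called them higher without Control 2 (adjusted p = 0.0412, median 0.48), and their median was 0.87 without Control 3. With any 1 library left out the medians lay between −0.45 and −0.06 for cholesterol, −0.04 (without AIH 2) and 0.41 for the unfolded protein response, −0.15 and 0.10 for oxidative stress and −0.25 and 0.23 for apoptosis genes, so the last 3 crossed 0. The medians of the T cell receptor, TGF-beta, oxidative stress and NK cell lists took the other sign with library totals as the scaling.

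At the level of single transcripts, the genes described above had no transcript past the test. Of 17999 transcripts tested with edgeR's quasi-likelihood test, 0 passed after Benjamini-Hochberg adjustment; 748 had an unadjusted p under 0.05, where chance gives 899.95. DESeq2 called 198, of which 104 were higher, and the fit without the filter called 24. In data simulated with the spread of these libraries, the same test found 0% of transcripts that differed 4-fold and 0.901% of those that differed 8-fold.

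The share of a gene taken by each of its transcripts was compared in 3779 genes with 10961 transcripts, and no named gene passed that test. By edgeR's test of transcript usage on the quasi-likelihood fit, 0 genes passed after Benjamini-Hochberg adjustment of the Simes p-values, and 104 had an unadjusted p under 0.05, where chance gives 189. The limma test on voom values called 18 genes and the likelihood-ratio fit 102, of which 50 and 52 had the lead transcript higher and lower. In simulated data with the spread of these libraries, the test found 0 of 200 swapped genes and the likelihood-ratio fit 13, with 29 false calls.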

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

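The fits without AIH 1 and Control 3, with the macrophage mean as a covariate and by likelihood ratio for usage were chosen after the results were seen. Of the named genes, 166 of the values under alternatives kept their direction and their side of the threshold, 99 lost the threshold, 13 gained it and 7 took the other sign; for the called lists, by the direction of their test, these were 112, 67, 0 and 1. The 10 called genes kept their sign under all 15 alternatives but passed the threshold in 4 to 6 of them. The gene count of 10 was 3 with library totals (Ccl3, Klf2 and Samsn1), 32 without the filter (24 higher, 8 lower), 337 with DESeq2's Wald test, 21 with limma-voom, 0 with the replicate block, 0 with the macrophage covariate and 1 without AIH 1 and Control 3; with 1 library left out it lay between 0 and 1. DESeq2's size factors kept the 10 calls, and so did the filter at 10 CPM, which added H2-Ab1. Of the 14 lists that filter kept 11. It lost oxidative phosphorylation (adjusted p = 0.0845 by camera) and left the endothelial and red cell lists with too few members to test. Library totals kept 13 lists, without oxidative phosphorylation. No label says that the replicate numbers pair the libraries. The deviations of AIH and Control 1, 2 and 3 from their group means correlated by 0.0132, 0.00134 and 0.191. Between unlike numbers the values ran from −0.122 to 0.108, so these few values cannot settle whether the libraries are paired. The block left 11 lists called, without oxidative phosphorylation, heat shock and antigen presentation, and changed no count of transcripts or usage. Against 14 called lists, 0 were called with an estimated correlation, 3 with fry, 5 with the macrophage covariate (4 of the 14 and the hepatocyte list) and 9 to 14 with 1 library left out, where 9 to 12 of the 14 were kept and up to 4 other lists gained a call. The macrophage covariate takes out the macrophage list's own difference by construction. It also separated the groups, so it can take up part of any other group difference, whatever the cause. Of 0 transcripts called by edgeR, DESeq2 gave 198 and the fit without a filter 24; of 0 usage calls, limma's test gave 18 and the likelihood-ratio fit 102. Il2ra, at −0.04, lay between −0.44 and 0.20 with 1 library left out (0.20 without AIH 1, 0.03 without AIH 2, 0.11 without Control 3), at 0.36 without AIH 1 and Control 3 and at 0.71 with the covariate. Ctla4 lay between −0.032 (without AIH 2) and 0.66 with 1 library left out, Ikzf2 was −0.13 with the covariate, and the red cell list's median took the other sign in 2 fits, at 0.54 with the covariate and 0.09 without AIH 1 and Control 3. Fewer libraries, or the degree of freedom a block or covariate takes, leave less to estimate the spread; otherwise the cause was not tested. The spread between libraries, more than depth, limits these tests: at 17780509 to 24572388 counts the floor was 0.160 CPM or less, while 8-fold changes were recovered for 37.2% of simulated genes.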

Other observations

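Genes chosen after their values were seen described further features of the libraries labelled AIH, none past the adjusted threshold by edgeR's quasi-likelihood test. Penk, which encodes the precursor of enkephalins, was at 329.7 ± 213 against 4.08 ± 5.30 CPM in the controls (SD, n = 3 per group), a log2 fold change of 6.33 (adjusted p = 0.300). Sdf4 was at 909.9 ± 187 against 254 ± 38.2 CPM (adjusted p = 0.0581), and Cst7, a cystatin gene of cytotoxic cells, at 414 ± 105 against 82.8 ± 35.8 CPM (0.134). Of the T cell receptor complex, 2 genes were higher in every library labelled AIH than in every control, Cd3g at 3119.8 ± 113 against 1304 ± 446 CPM (0.319) and Cd3d at 2155 ± 69.8 against 1237 ± 233 CPM (0.427), while the groups overlapped for Cd3e, at 215 ± 187 against 85.4 ± 29.6 CPM. Fasl, the death ligand of activated T cells, was at 80.5 ± 42.6 against 16.3 ± 8.93 CPM (0.421), and Skil, a TGF-beta pathway inhibitor, at 1138 ± 470 against 403 ± 96.9 CPM (0.319).

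The tests of fewer Treg cells, of macrophage RNA and of NK cells, and the splits for transcript usage, were chosen after the result was seen. For the counts of calls, the 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 10 genes and the other splits at most 0, so 1 of the 10 splits gave as many. It called 14 lists and the others at most 6, again 1 of 10, so camera called lists in splits that do not follow the labels. All 10 splits gave at least the 0 transcripts and at least the 0 usage genes of the real split, with at most 0 and 2 in the others. The likelihood-ratio fit called 102 usage genes in the real split, fewer than 6 of the others, which reached 280.

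Foxp3 was low in the libraries labelled AIH, against the sort for its reporter. Replacement of Treg cells by cells that lack the other Treg genes would lower those genes about as far as Foxp3, at −3.54; the median log2 fold change of the 20 other Treg identity genes was 0.41 with an SD of 1.13, which argues against it. For the size of the fall, random dropout of a weakly expressed gene is unlikely as well. Of the 200 genes nearest in mean CPM, 1.5% fell as far, under the 5% set as the bound. The lack of overlap was less rare, since 10.5% of these 200 genes had every library labelled AIH below every control. That share counts this direction only, while the 10% that chance gives covers both directions. What stays open is whether Foxp3 mRNA was lost in cells that kept the reporter protein, and whether activated T cells without Foxp3, which share many of these genes, passed the sort; the disease itself was not tested apart from these. The log2 fold change lay between −4.64 and −2.96 with any 1 library left out and was −1.58 (SE 1.51) with the macrophage mean as a covariate.

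Macrophage and class II genes were lower in the libraries labelled AIH. A candidate explanation is more macrophage RNA in the control libraries. How fully the sort on GFP removed macrophages was not tested. The 16 macrophage genes rose and fell together within the groups, with a median correlation of 0.764. In 1000 lists of the same size and expression it had a median of 0.0229 and reached at most 0.433. The most abundant of them, Lyz2 and C1qb, reached 3225 and 3362 CPM in Control 3. The list's median was −1.23 without Control 3, beyond the bound of −1, which argues against Control 3 alone as the source. Whether cells attached to macrophages, free RNA or the disease set this difference stays open, and so does how far it moves the T cell lists. The covariate cannot decide this, since it separated the groups and can take up any difference between them. With it camera kept the resting and immediate early lists. Of the T cell lists camera lost, the medians went from 1.01 to 0.85 for Treg suppression and 0.61 to 0.54 for tissue Treg. They went from 0.70 to 0.51 for NF-kB, but from 0.54 to 0.08 for Th1-type genes.

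NK cells could bring the chemokine genes Ccl3, Ccl5 and Xcl1, which rose in the libraries labelled AIH. How fully the sort on Foxp3-GFP removed NK and CD8 T cells was not tested. The 3 genes had a median log2 fold change of 3.88, and the 8 NK markers outside the T cell lists had a median of −0.28 with an SD of 2.03. The marker median thus lay lower by more than that SD. It rests partly on Tyrobp and Fcer1g, at −1.79 and −1.76, which are also macrophage genes. Klre1 was at 4.15, and the median of the whole NK list, 0.15, was −1.31 without AIH 1. These markers therefore do not settle whether NK cells were a source. For CD8 T cells, Cd8a had a log2 fold change of 2.53 and Cd8b1 0.96. The groups overlapped for Cd8b1 and not for Cd8a. In AIH 1 and AIH 3 Cd4 was at 49.3 and 28.3 CPM, below Cd8a (119 and 132 CPM) and Cd8b1 (87.6 and 177 CPM). In AIH 2 and in every control Cd4 was higher than both. CPM do not correct for length, so levels of different genes compare only roughly. The values of AIH 1 and AIH 3 go with CD8 T cells. They do not settle whether CD8 T cells or activated Treg cells brought the chemokine genes. With the macrophage mean as a covariate Ccl3 went from 3.77 (SE 0.43) to 3.29 (SE 0.56) and Klf2 from −2.77 (SE 0.31) to −2.45 (SE 0.42), and both lost their call as the SEs grew and a degree of freedom was spent. Activation of Treg cells by the disease remains an untested hypothesis beside these.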
